A study of Sorghum bicolor with 14 samples.

How the data were processed

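Middle internodes of 14 samples were analysed, 2 in each of 7 groups. Per the labels, total RNA was made into libraries with a stranded total RNA kit. Per the file headers, the deposited values are FPKM, given by the authors as 1 value per gene and group in 2 tables placed side by side, the first for the 4 stages and the second for the 3 soil moisture readings. How the 2 samples of a group were combined is not given in the sources used here. The submitters' processing notes name cutadapt 1.8.1, Bowtie2 2.2.9, HISAT2 2.0.5 and Cuffdiff without their roles. The genome build is not given in the sources used here. Gene models carry Sobic names and the suffix v3.2, and coordinates are those of the file. Each table has its own locus identifiers and row order, and the 2 were taken as normalised separately. FPKM values keep no count of reads, so the depth of each sample and the precision it gives are unknown, and reads shared between overlapping loci could have been split in ways the values do not show.

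The development table held 34755 rows, of which 2003 had no gene name and were left out (282 of them reached 10 FPKM in a stage). The drought table held 32726 rows. Several gene models shared 1 row in 1213 and 1230 cases, and 4774 and 4762 named rows shared their locus with another row. Rows were matched between the tables by name, which 32028 names found once in each table allowed, 26825 of them with identical coordinates. A gene was measured when it reached 1 FPKM in at least 1 column of the table, which left 18338 genes in the development table, 16801 in the drought table and 16817 matched genes. There were 0 value columns that were not used.

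The groups, comparisons, gene lists and alternatives were fixed before the data were examined. The planned test, limma on log2(FPKM + 1) over all samples, needs a value per sample. With 1 value per group it could not be applied, and the fallback fixed with it was used, which gives values and folds with no test. The planned filter, which counted samples, was replaced by the one above for the same reason. The pseudocount was 1 FPKM and a gene counted as different at a log2 change of at least 1. Pearson's r was taken across genes on the log2 scale.

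Genes were to be named by size of change and by list. Of the 34 lists, 28 were to be filled by gene descriptions, which the tables used here do not pair with the identifiers, and these had no members. The other 6 lists held Sobic identifiers fixed in advance, of which 27 are analysed and 1 is not reported here. Their names come from published work on these loci and not from the tables. Any further genes of the same families, which descriptions were to supply, were not included. Counts such as all 3 cellulose synthases therefore refer to the list and not to the gene family. NAC factors and dhurrin synthesis held 1 gene each. The sucrose list had 4 measured genes of 6 and the transporter list 7 of 10, the rest staying under 1 FPKM. In the drought table vacuolar invertase was not measured either. A further 10 identifiers (dhurrin cluster, clock and stem height genes) were chosen after the data were seen. Beyond the lists, the 2 genes with the largest increase and the 2 with the largest decrease are named per comparison by identifier alone, leaving out rows listed at 0 in either group and rows whose higher value was under 5 FPKM. That rule was set after the table was seen.

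For lists with at least 5 measured genes, the median log2 change was placed among 10000 random lists of equal size, each member drawn from the 200 genes nearest in mean expression. This percentile describes these columns and is not a test. The code was run on simulated data. Of 100 random lists, 2 fell outside the central 95% of the percentiles for B vs FI, over 18338 genes, and 7 for D2 vs D1, over 16801 genes. With 1 value per group and a fixed threshold, such a run gives no error rate for the calls. The simulated noise was drawn independently for each gene and the lists at random, so about 5% outside is given by construction. The run therefore does not show how often lists of related genes, which may vary together, reach extreme percentiles. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median ratio rescaling and quantile normalization. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.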

Results

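RNA was sequenced from the middle stem internode of the sweet sorghum (Sorghum bicolor) variety CSV24SS. Sweet sorghum is a cereal grown for the sucrose stored in its stem juice. The 14 samples formed 7 groups of 2. In the development series, plants in a fertilised soil bed were sampled at 4 stages. These were floral initiation (FI), booting (B, when the panicle is still inside the flag leaf sheath), and the milky (MS) and soft dough (SD) stages of grain filling. In the drought series, plants grew in pots and were no longer watered from the flag leaf stage on. They were sampled at booting, when the soil held about 13% (D1), 7% (D2) or 2% (D3) moisture. The series has no group of watered pots, so soil moisture cannot be told apart from the time since watering stopped. Both series ask which genes differ in the stem, in the first as the plant matures and in the second as the soil dries.

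The values are FPKM (fragments mapped to a gene, scaled to its length and to the sequencing depth), with 1 value by the authors per gene and group. The 2 samples of a group were not given separately, so no difference below could be set against a spread between replicates. No test was run, and higher and lower describe 2 values. The table gave no read counts, so the depth of the samples is unknown. Changes are differences in log2(FPKM + 1), which understate the change of weakly expressed genes. Folds are ratios of the FPKM values themselves. A gene was counted as different when the log2 change was at least 1, that is 2-fold. At least 1 FPKM was reached by 16902 genes in FI, 15715 in B, 15835 in MS and 16210 in SD, and by 16039 in D1, 15581 in D2 and 16077 in D3.

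Of 18338 genes measured in the development series, 8903 (48.5%) differed at least 2-fold between their highest and lowest stage. The highest value of these fell in FI for 3695 genes, in SD for 2200, in B for 1765 and in MS for 1243. The 2 highest values were FI and B for 2175 genes, FI and SD for 2055 and MS and SD for 1771. Values were higher at each successive stage for 559 genes and lower at each for 842. In the drought series, 2567 of 16801 genes (15.3%) differed at least 2-fold among the 3 soil moisture readings. A range over 4 stages tends to exceed one over 3 readings, and genes were filtered per series, so these shares are not comparable.

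**Figure D1:**
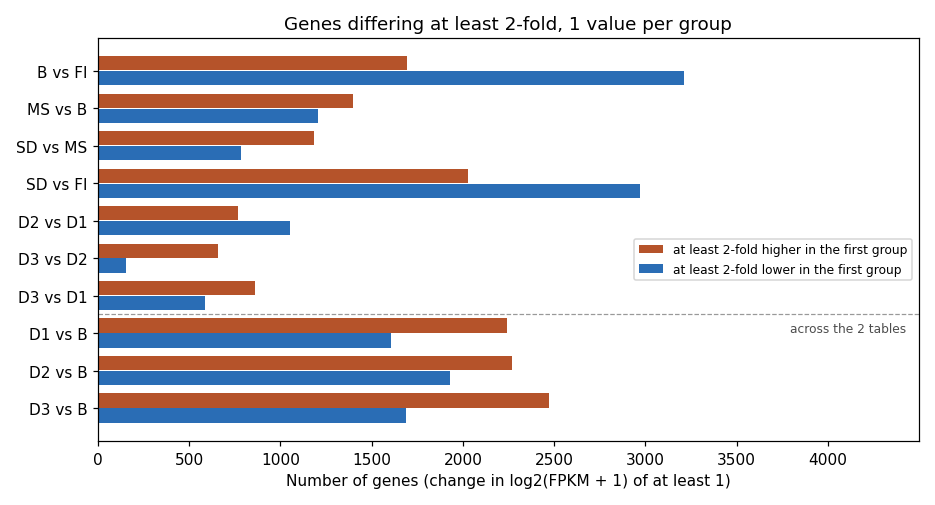
Numbers of genes at least 2-fold higher (orange) or lower (blue) in the first group of each comparison, from 1 value per group. The largest bar is the 3212 genes lower at booting than at floral initiation and the smallest is the 152 genes lower in D3 than in D2; the lowest 3 comparisons set values from separate tables against each other.

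At booting compared with floral initiation, 2 SWEET genes were at least 2-fold higher and all 3 listed cellulose synthase genes lower. Of 7 measured transporters, 2 were at least 2-fold higher, 0 were lower and 5 lay within 2-fold. Both of the higher ones encode SWEET proteins, which release sugars across membranes. Sobic.008G094000 (chromosome 8, 43917194 to 43919961) was at 44.8 FPKM in FI and 210 in B, a 4.68-fold difference, and Sobic.004G133500 (chromosome 4, 21147713 to 21152806) was 2.48-fold higher. The vacuolar sugar importers TST1 and TST2 were at 177 and 130 FPKM in FI and at 269 and 237 in B. All 3 listed cellulose synthase genes were at least 2-fold lower, the most abundant of them, Sobic.002G118700 (chromosome 2, 14784463 to 14790415), by 6.94-fold from 569.9 to 82.1 FPKM. With a pseudocount of 5, Sobic.001G224300 among them and the vacuolar invertase described next fell short of 2-fold.

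The dry-stalk NAC gene Sobic.006G147400 (chromosome 6, 50895748 to 50899172), the transcription factor gene of the locus that separates pithy from juicy stems, was at 8.53 FPKM in FI and 158 in B, 18.6-fold higher. In sucrose metabolism 1 of 4 measured genes was higher, 1 lower and 2 within 2-fold. The vacuolar invertase Sobic.004G004800, which splits stored sucrose, was at 2.32 and 9.61 FPKM, and the sucrose synthase Sobic.001G344500 at 388 and 110 FPKM. Of the 6 lignin genes, PAL (Sobic.004G220300, phenylalanine ammonia-lyase, the entry enzyme of the pathway) was 3.93-fold lower, at 4139 and 1053 FPKM. C4H (Sobic.002G126600, cinnamate 4-hydroxylase) was 2.14-fold higher and the other 4 lay within 2-fold. After median ratio rescaling 0 lignin genes were at least 2-fold higher. PAL values are uncertain because rows of neighbouring genes cover the same locus. CYP79A1 (Sobic.001G012300, chromosome 1, 1144010 to 1146367), the first enzyme of the synthesis of the cyanogenic glucoside dhurrin, was 16.8-fold lower, at 51.4 and 3.06 FPKM. The clock gene LHY (Sobic.007G047400), chosen after its values were seen, was 10.7-fold higher.

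The largest log2 increases from FI to B were 7.85 for Sobic.004G007300 (chromosome 4, 646026 to 651065) and 6.90 for Sobic.009G246000 (chromosome 9, 58162911 to 58165477). The largest decreases were -8.78 for Sobic.009G014600 (chromosome 9, 1267111 to 1268591) and -8.60 for Sobic.001G301500 (chromosome 1, 58340491 to 58342011). Altogether 1696 genes were higher and 3212 lower, with Pearson's r of 0.838 across genes, which are not independent replicates. The 2 scalings moved this split in opposite directions. After quantile normalization it was 2246 higher and 2606 lower, and the median over all genes moved from 0.00 to 0.12. After median ratio rescaling it was 1451 higher and 3516 lower, with a median of -0.0985. The median change of the transporters was 0.60, at percentile 91.4 of 10000 random lists of equal size matched on mean expression, and that of the lignin genes was -0.32, at percentile 8.25.

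At the milky stage compared with booting, 2 of the 3 listed cellulose synthases and 2 of the 6 listed lignin genes were at least 2-fold lower. The cellulose synthases Sobic.001G224300 (chromosome 1, 21485581 to 21489706) and Sobic.003G296400 (chromosome 3, 62851273 to 62857742) were 6.74-fold and 6.62-fold lower, at 12.9 and 23.4 FPKM in B and 1.91 and 3.54 in MS. The third, Sobic.002G118700, was 1.70-fold higher. Of the lignin genes, 0 were higher and the other 4 lay within 2-fold. PAL was at 343 FPKM in MS, 3.07-fold lower, and CAD (Sobic.004G071000, cinnamyl alcohol dehydrogenase, which acts at the last step) was at 100 FPKM in B and 43.9 in MS. The lignin median of -0.57 lay at percentile 1.48 of the matched random lists.

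All 7 measured sugar transporters lay within 2-fold between B and MS, 6 of them lower at MS, with a median of -0.25 at percentile 8.28. Among the sucrose synthases, which cleave sucrose reversibly, Sobic.001G378300 (chromosome 1, 66642502 to 66650446) was higher, at 20.7 and 71.1 FPKM. The more abundant Sobic.010G072300 (chromosome 10, 5859073 to 5867276) was lower, at 818 and 371 FPKM, and the other 2 measured genes of the list lay within 2-fold. The dry-stalk NAC gene was 2.94-fold lower at MS, at 53.9 FPKM, and CYP79A1 was 2.43-fold higher, at 7.44 FPKM. On the log2 scale the latter fell short of 2-fold after quantile normalization and with a pseudocount of 5. The largest increases were 7.78 for Sobic.007G213800 (chromosome 7, 64257506 to 64258292) and 7.32 for Sobic.001G418600 (chromosome 1, 69932393 to 69935701). The largest decreases were -7.98 for Sobic.004G007300 and -7.00 for Sobic.009G246000, which had shown the largest increases from FI to B. In all, 1400 genes were higher and 1204 lower (r of 0.923 across genes).

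At soft dough compared with the milky stage, all 3 listed cellulose synthases were at least 2-fold higher. Sobic.003G296400 was 6.22-fold higher, Sobic.001G224300 5.09-fold higher at 9.73 FPKM and Sobic.002G118700 2.46-fold higher at 343 FPKM. CCoAOMT (Sobic.010G052200, caffeoyl-CoA O-methyltransferase) was the 1 lignin gene at least 2-fold higher, at 524 and 1115 FPKM, and the other 5 lay within 2-fold. The lignin median was 0.18 at percentile 69.1. Vacuolar invertase was lower, at 8.79 and 1.95 FPKM, as was the sucrose synthase Sobic.001G378300 at 71.1 and 21.9 FPKM. The other 2 genes of the sucrose list lay within 2-fold.

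TST2 was the 1 of 7 transporters at least 2-fold lower at SD, at 199 and 91.0 FPKM, and TST1 was at 261 and 138 FPKM. The remaining 6 lay within 2-fold, although after quantile normalization 2 of 7 were past it. The median of this list was 0.13, at percentile 68.5, while its mean was -0.20. The dry-stalk NAC gene was 2.11-fold higher, at 113 FPKM, and CYP79A1 4.66-fold higher, at 34.6 FPKM. After quantile normalization the NAC gene fell short of 2-fold, as did vacuolar invertase with a pseudocount of 5. LHY was 5.17-fold lower and the clock gene TOC1 (Sobic.004G216700, also chosen after its values were seen) 3.12-fold higher. The largest increases were 4.46 for Sobic.006G025900 (chromosome 6, 4669311 to 4670061) and 4.33 for Sobic.002G416600 (chromosome 2, 76400758 to 76402443). Decreases reached -4.80 for Sobic.009G234600 (chromosome 9, 57389227 to 57390570) and -4.46 for Sobic.001G334501 (chromosome 1, 62342118 to 62343997). This step had 1186 genes higher and 783 lower, the fewest of the 3 consecutive steps, and r of 0.952 across genes.

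Between the first and last stage, the dry-stalk NAC gene was 13.3-fold higher at soft dough than at floral initiation. PAL was 16.5-fold lower, at 4139 and 250.5 FPKM. C4H was 2.38-fold higher, and the other 4 lignin genes lay within 2-fold. The lignin median was -0.64, at percentile 2.58. The cellulose synthases Sobic.001G224300 and Sobic.003G296400 were 3.11-fold and 2.85-fold lower, and Sobic.002G118700 was 1.66-fold lower.

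The SWEET gene Sobic.008G094000 was 3.06-fold higher at SD than at FI. The vacuolar sucrose transporter SUT4 (Sobic.008G193300) was the 1 transporter at least 2-fold lower, at 164 and 67.6 FPKM. The other 5 lay within 2-fold, and the list median was 0.54 at percentile 80.1. The sucrose synthases Sobic.010G072300 and Sobic.001G344500 were lower, the first at 1242 and 441 FPKM and the second at 388 and 119 FPKM. CYP79A1 was 1.48-fold lower. The largest increases were 5.51 for the row of Sobic.010G032000 and Sobic.010G032100 (chromosome 10, 2573464 to 2576676) and 5.49 for that of Sobic.006G158600 and Sobic.006G158700 (chromosome 6, 51704534 to 51710864). The largest decreases were -8.19 for Sobic.003G338801 (chromosome 3, 66191753 to 66194027) and -7.98 for Sobic.003G298700 (chromosome 3, 63004845 to 63006319). The comparison gave 2030 genes higher and 2969 lower (r of 0.858 across genes). The split was 2405 and 2615 after quantile normalization, but 1820 and 3166 after median ratio rescaling. It was 1510 and 1567 among genes with a mean of at least 5 FPKM.

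**Figure D2:**
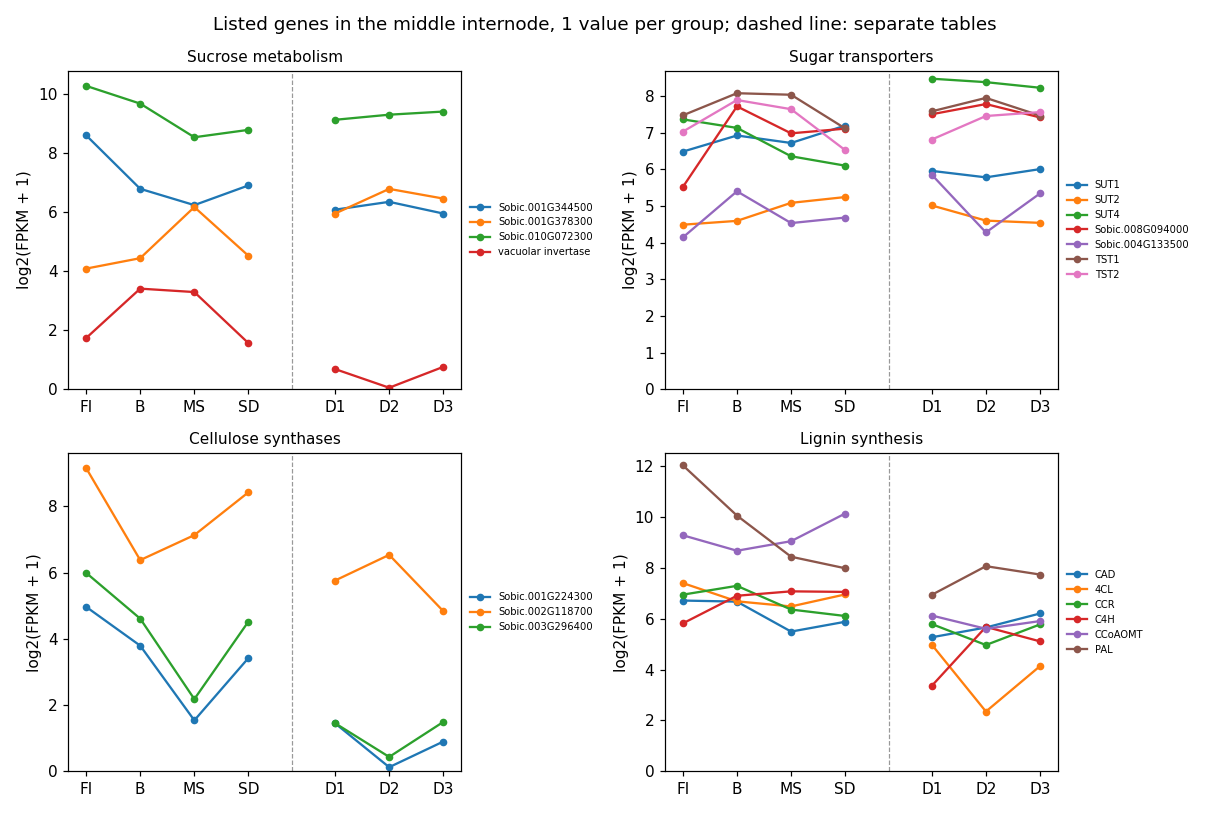
Expression as log2(FPKM + 1) of the measured genes of 4 lists in the 7 groups, with 1 point per gene and group and lines joining groups of 1 table. The cellulose synthases Sobic.001G224300 and Sobic.003G296400 were lowest among the stages at MS, at 1.91 and 3.54 FPKM. The 6 lignin genes lay lower in D1 than in B. The dashed line parts the 2 tables, which were taken as separately normalised.

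In the drought series, the step from D1 to D2 had opposite changes among the lignin genes. C4H was 5.41-fold higher in D2, at 9.26 and 50.1 FPKM, and PAL was 2.19-fold higher. 4CL (Sobic.004G062500, 4-coumarate CoA ligase) was 7.43-fold lower, at 30.4 and 4.10 FPKM, and the other 3 lay within 2-fold. PAL fell short of 2-fold after quantile normalization. The list median was -0.07, at percentile 14.4. The cellulose synthases Sobic.001G224300 and Sobic.003G296400 were lower, at 1.74 FPKM each in D1 and 0.0922 and 0.354 in D2. The latter fell short of 2-fold after quantile normalization, and both did with a pseudocount of 5. Sobic.002G118700 was 1.72-fold higher.

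The SWEET gene Sobic.004G133500 was 3.09-fold lower in D2, at 56.8 and 18.4 FPKM. The other 6 transporters lay within 2-fold, with a list median of -0.09 at percentile 7.35. The 3 sucrose synthases measured here lay within 2-fold and were higher in D2, Sobic.001G378300 at 60.9 and 109 FPKM. The dry-stalk NAC gene was within 2-fold and lower in D2, at 119 and 66.2 FPKM, and passed 2-fold after quantile normalization. CYP79A1 stayed under 1 FPKM in all 3 drought columns. Among the clock genes, LHY was 5.51-fold higher and TOC1 2.26-fold lower in D2, and GI (Sobic.003G040900, added in the same way) was 1.35-fold higher. The largest increases were 5.52 for Sobic.003G039400 (chromosome 3, 3695195 to 3696666) and 5.28 for Sobic.008G105500 (chromosome 8, 49760625 to 49764366). The largest decreases were -4.92 for Sobic.010G016500 (chromosome 10, 1315564 to 1316314) and -4.44 for Sobic.002G345200 (chromosome 2, 71127202 to 71128757). In all, 768 genes were higher and 1050 lower (r of 0.941 across genes), but 598 and 627 among genes with a mean of at least 5 FPKM. The split was 794 and 919 after quantile normalization and 732 and 1100 after median ratio rescaling.

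From D2 to D3, more genes were higher than lower, 659 against 152, and r across genes was 0.968. 4CL was 4.04-fold higher in D3, at 16.6 FPKM, the 1 lignin gene at least 2-fold different, and the other 5 lay within 2-fold. The lignin median of 0.43 lay at percentile 99.8, with 4 genes higher and 2, C4H and PAL, lower in D3. The level of 4CL in D3 stayed below its 30.4 FPKM of D1. The cellulose synthase Sobic.003G296400 was higher, at 0.354 and 1.81 FPKM, which fell short of 2-fold after quantile normalization and with a pseudocount of 5. Sobic.001G224300, at 0.0922 and 0.868 FPKM, differed by less than 1 on the log2 scale but passed 1 with a pseudocount of 0.1. Sobic.002G118700 was 3.33-fold lower, at 91.8 and 27.6 FPKM. The SWEET gene Sobic.004G133500 was 2.15-fold higher, at 39.6 FPKM, but not with a pseudocount of 5. The other 6 transporters lay within 2-fold. Their list median was -0.06, at percentile 72.1, with a mean of 0.05 and a median of 0.01 after quantile normalization.

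The 3 sucrose synthases lay within 2-fold between D2 and D3, and the dry-stalk NAC gene was 1.27-fold higher in D3, at 84.3 FPKM. The largest increases lay on 1 stretch of chromosome 6. Sobic.006G025900 was at 0.0431 FPKM in D2 and 439 in D3, and the row of Sobic.006G025400 and Sobic.006G025700 (4498652 to 4561012), which shares its locus with other rows, was at 0.181 and 206 FPKM. Decreases reached -3.39 for Sobic.003G085300 (chromosome 3, 7351048 to 7362566) and -3.07 for Sobic.010G164500 (chromosome 10, 48651082 to 48652795).

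Between the driest and the wettest reading, C4H was 3.61-fold higher in D3 than in D1, the 1 lignin gene past the threshold. The other 5 lay within 2-fold, CAD at 37.5 and 72.5 FPKM among them, and the list median of 0.39 lay at percentile 94.9. On the log2 scale all 7 measured transporters, all 3 listed cellulose synthases and the 3 measured sucrose synthases lay within 2-fold. The FPKM ratio of the cellulose synthase Sobic.001G224300 was 2.00, at 1.74 FPKM in D1 and 0.868 in D3. After quantile normalization 1 cellulose synthase, Sobic.002G118700, was past 2-fold lower. The transporter median was -0.12, at percentile 13.3. The dry-stalk NAC gene was 1.41-fold lower in D3. LHY was 3.57-fold higher and TOC1 1.57-fold lower. The largest increases were 6.93 for Sobic.006G026000 (chromosome 6, 4676586 to 4678325) and 6.91 for the row of Sobic.006G025400 and Sobic.006G025700. Sobic.006G025900 was listed at 0 in D1 and was left out here. Decreases reached -4.35 for Sobic.002G275500 (chromosome 2, 65814915 to 65825791) and -3.90 for a row of 4 gene models starting with Sobic.001G166200 (chromosome 1, 13830747 to 13843504). In all, 861 genes were higher and 587 lower (r of 0.948 across genes).

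Each drought column was also set beside the booting plants of the soil bed. These levels come from tables taken as separately normalised, and the plants also differed in pot against soil bed and in watering, which cannot be told apart. The time of day at harvest is not given and may have differed too. The same booting column entered all 3 comparisons. Lignin genes were lower in the drought columns. All 6 were at least 2-fold lower in D1 and in D2 than in B, and 5 of 6 in D3, with list medians of -2.12, -2.15 and -2.05. Each median lay below those of all 10000 matched random lists. The exception was CAD in D3, at 72.5 against 100 FPKM. CAD in D2 fell short of 2-fold with a pseudocount of 5. PAL was 8.69-fold, 3.97-fold and 4.99-fold lower in D1, D2 and D3, although its row ends at 57086639 on chromosome 4 in the development table and at 57069724 in the drought table. CCoAOMT was at 404 FPKM in B and between 47.4 and 68.5 in the drought columns.

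The cellulose synthases Sobic.001G224300 and Sobic.003G296400 were at least 2-fold lower in each drought column, the latter by 13.5-fold, 66.2-fold and 12.9-fold. Sobic.002G118700 was at least 2-fold lower in D3 alone, by 2.98-fold. Vacuolar invertase, at 9.61 FPKM in B, stayed below 1 FPKM in D1, D2 and D3. The sucrose synthase Sobic.001G378300 was higher in all 3, at 60.9, 109 and 87.0 FPKM against 20.7, and the other 2 measured sucrose synthases lay within 2-fold. Among the 7 transporters SUT4 was at least 2-fold higher in each, at 355, 332 and 299 FPKM against 139 in B. TST2 was lower in D1, at 111 FPKM, and the phloem sucrose transporter SUT1 (Sobic.001G488700) and Sobic.004G133500 were lower in D2, at 54.0 and 18.4 FPKM, the latter gene not with a pseudocount of 5. After median ratio rescaling, 2 transporters rather than 1 were at least 2-fold lower in D1. The SUT1 row spans 75789008 to 75923262 on chromosome 1 in the drought table, against 75891907 to 75897861 in the other, so its drought values are uncertain. The list medians were -0.21, -0.13 and -0.30, at percentiles 24.2, 15.9 and 10.8.

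The dry-stalk NAC gene was 1.33-fold, 2.39-fold and 1.88-fold lower in D1, D2 and D3 than in B. CYP79A1, at 3.06 FPKM in B, was at 0.0136, 0.00915 and 0.00736 FPKM, differences that fell short of 2-fold with a pseudocount of 5. LHY was 24.7-fold, 4.49-fold and 6.92-fold lower. In D1 the largest increases were 7.69 for Sobic.005G157600 (chromosome 5, 62968476 to 62970416) and 6.85 for Sobic.009G116700 (chromosome 9, 45915614 to 45916682). In D2 they were 7.32 for Sobic.001G291300 (chromosome 1, 56808443 to 56809248) and 6.99 for Sobic.002G141800 (chromosome 2, 23093097 to 23093995). In D3 they were 8.27 for Sobic.006G025900 and 7.18 for Sobic.001G291300.

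**Figure D3:**
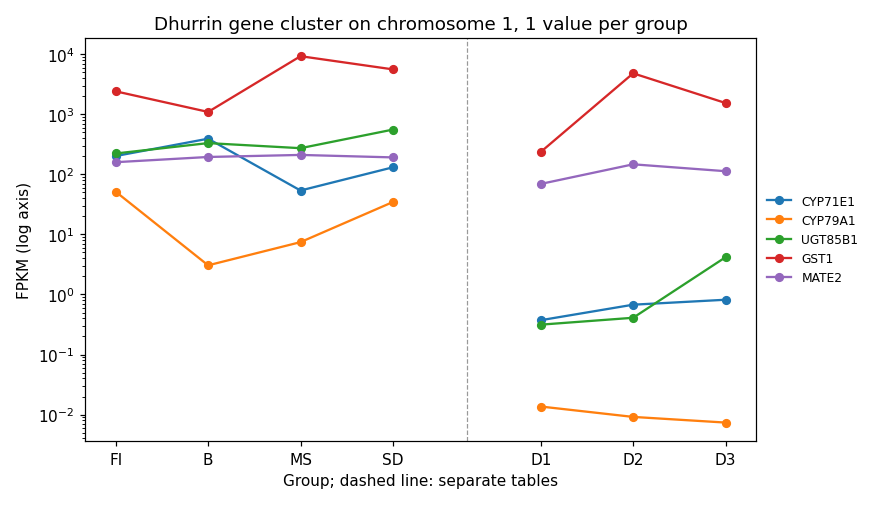
FPKM on a log axis of 5 neighbouring genes of the dhurrin cluster on chromosome 1 in the 7 groups, with 1 point per gene and group and lines joining groups of 1 table. CYP79A1, CYP71E1 and UGT85B1 lay at 4.17 FPKM or less in the 3 drought columns, while GST1 and MATE2 lay at 69.3 FPKM or more there; 4 of the 5 genes were added after the data were seen.

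The largest decreases against B in D1 and D3 included the dhurrin gene CYP71E1 (Sobic.001G012200, chromosome 1, 1048570 to 1050688), with changes of -8.16 and -7.76. In D2 they included UGT85B1 (Sobic.001G012400, chromosome 1, 1152500 to 1153979), the glucosyltransferase of that pathway, with -7.88. In all 3 columns the row of Sobic.003G385500 and Sobic.003G385900 (chromosome 3, 69796878 to 69830766) was the other, at -7.98, -8.08 and -7.20. Of 16817 genes matched between the tables, 2244 were higher and 1607 lower in D1 than in B, 2267 and 1930 in D2, and 2472 and 1687 in D3, with r of 0.869, 0.868 and 0.865 across genes. After median ratio rescaling D2 had 2001 genes higher and 2137 lower, and after quantile normalization the splits were 1971 and 1845, 2045 and 1989, and 2116 and 2027.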

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

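No paired analysis was possible because the table holds 1 value per group. Leaving out single samples, separate fits per series and the limma, camera and fry tests were not run for the same reason. The settings without genes listed at 0 and with identical loci were chosen after seeing the data. Counts of genes at least 2-fold different kept within 1.5 times their main value under median ratio rescaling, quantile normalization and without genes listed at 0, and with identical loci, run only for the drought columns against B. Leaving out genes listed at 0 or with differing loci only removes genes, so those counts can only be lower and say little about stability. With identical loci they were 2870 for D1 vs B, 3158 for D2 vs B and 3173 for D3 vs B. Dropping the filter changes nothing by construction, since a gene under 1 FPKM in every column cannot reach a log2 change of 1, so it tests nothing. With a pseudocount of 0.1 the counts were 3932 for MS vs B, 3212 for SD vs MS, 2728 for D2 vs D1, 1356 for D3 vs D2 and 2265 for D3 vs D1, as weakly expressed genes enter by construction. With a pseudocount of 5 they were 2483 for B vs FI, 1221 for MS vs B, 957 for SD vs MS, 2600 for SD vs FI, 863 for D2 vs D1, 362 for D3 vs D2, 655 for D3 vs D1, 1998 for D1 vs B, 2181 for D2 vs B, 2186 for D3 vs B, 4814 across development and 1205 across soil moisture. With a mean of at least 5 FPKM, which leaves fewer genes, they were 2865 for B vs FI, 1653 for MS vs B, 3077 for SD vs FI, 461 for D3 vs D2, 903 for D3 vs D1, 5431 across development and 1593 across soil moisture. Of the 311 changes of single named genes under 4 settings each, 1191 values moved by less than 1.5-fold, 53 by more, and 0 of those at least 2-fold changed direction. These genes include those added after the data were seen. Calls at the 2-fold threshold did change: 17 were lost with a pseudocount of 5, and 8 were lost and 3 gained after quantile normalization. Median ratio rescaling lost 1 and gained 2, and a pseudocount of 0.1 gained 3. Depth is unknown, so it cannot be said which low values it limits.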

Other observations

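A stretch of chromosome 6 held neighbouring genes that differed together in several comparisons. Between 4498652 and 4685808, 6 adjacent measured genes were higher in D3 than in D2 and than in D1, with median log2 changes of 6.91 and 6.49. Over 4498652 to 4684050, 6 adjacent genes had been lower at booting than at floral initiation, with a median of -6.22, and 5 adjacent genes from 4498652 to 4678325 were higher at soft dough than at the milky stage, with a median of 2.92. Sobic.006G025900 within it was at 496 FPKM in FI, 0.422 in B, 2.78 in MS and 82.5 in SD, and was listed at 0 in D1, at 0.0431 in D2 and at 439 in D3. A stretch of chromosome 7 (8904277 to 8924777) had 4 adjacent genes lower in D2 than in D1, with a median of -2.34, and higher in D3 than in D2, with a median of 4.22. Another on chromosome 6, from 57419856 to 57452200, had 6 adjacent genes higher at booting than at floral initiation, with a median of 3.39. Within it, 5 adjacent genes were lower at MS than at B (median -2.59) and 5 lower in D2 than in D1 (median -2.77). In D3 compared with D1, 4 adjacent genes there were lower, with a median of -1.79. From FI to B there were 53 runs of at least 4 adjacent genes differing at least 2-fold in 1 direction, 48 of them lower, against a mean of 15.3 and a maximum of 31 in 1000 permutations of gene order. From D1 to D2 there were 6 such runs, all lower, against a maximum of 3 in permutations. SD vs MS had 5 against a maximum of 4, and D3 vs D2 and D3 vs D1 had 4 each against 2. The runs did not exceed the permuted maximum for SD vs FI, with 23 against 23, or for MS vs B, with 5 against 5. Overlapping loci were reduced to 1 gene before runs were counted, and near-identical neighbours can share reads.

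The stem height genes Dw1, Dw2 and Dw3 were all measured. Dw3 (Sobic.007G163800), which encodes an auxin transporter, was at 22.2 FPKM in MS and 6.17 in SD. In the drought table it was at 11.5, 5.82 and 5.62 FPKM in D1, D2 and D3. Dw1 (Sobic.009G229800) lay between 7.55 and 17.3 FPKM in all 7 groups. Dw2 (Sobic.006G067700) was at 37.1, 32.7 and 18.0 FPKM in D1, D2 and D3. In the dhurrin cluster on chromosome 1, GST1 (Sobic.001G012500, a glutathione transferase gene) was at 1095 FPKM in B and 9283 in MS, and at 236, 4814 and 1542 FPKM in D1, D2 and D3.

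Of the tests below, the one on the separate normalization of the tables was set before its result was seen, and the others were chosen afterwards. Some very abundant genes were listed at exactly 0 in 1 or 2 columns of a table. Sobic.002G324200 (chromosome 2, 69501545 to 69504021) was at 12502 FPKM in FI, 0 in B and MS and 13868 in SD, and Sobic.001G141300 (chromosome 1, 11334814 to 11340551) was at 0 in D1 and 23987 in D2. Such zeros occurred in 2 of 111 genes reaching 1000 FPKM and 0 of 1900 reaching 100 to 1000 FPKM in the development table, and in 2 of 85 and 1 of 1642 in the drought table, while 0 genes reaching 1000 FPKM had a value between 0 and 1 FPKM, which is what failed estimates written as 0 may leave, although this rests on 2 genes per table. Among genes reaching 10 to 100 FPKM, where low values are common, 69 of 9061 had a 0 and 452 a value between 0 and 1 FPKM in the development table, and 1 and 45 of 8350 in the drought table. A true loss of the transcript was not excluded. Sobic.002G324200 was at 6377, 15546 and 12777 FPKM in D1, D2 and D3, also sampled at booting. Sobic.001G141300 was at 9873 FPKM or more in all 4 stages. Sobic.008G136000, at 0 in FI and B, was at 1435, 2638 and 2490 FPKM in D1, D2 and D3. In contrast, a row of several gene models starting with Sobic.010G182100 was at 2661, 0 and 2327 FPKM in D1, D2 and D3. It was at 0 in all 4 stages. Folds between columns without a 0 reached 327 in the development and 20.4 in the drought table among genes reaching 1000 FPKM. They reached 35601 among genes of 100 to 1000 FPKM in the development table.

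Of the 2567 genes that differed at least 2-fold across soil moisture, 2558 had no equal values, and D2 was the middle value for 739 of these (28.9%), where random order gives 33.3%, and D3 for 1375 (53.8%). A response growing steadily with drying would place D2 in the middle of most genes, but the error of each single column is unknown, so it is neither shown nor excluded. The share was 28.5% after median ratio rescaling and 35.7% after quantile normalization, so neither scaling put D2 in the middle of most genes. Whether the share lies below that of random order depends on the scaling between the columns, which stays open to that extent. A different time of day at harvest, which the labels do not give, also stays open: the log2 difference between the morning gene LHY and the evening gene TOC1 was -3.83 in D1, -0.36 in D2 and -1.48 in D3, a change of 3.47 from D1 to D2 with D3 between them, but GI, another evening gene, was 1.35-fold higher in D2, where LHY was higher too. The same difference was 0.20 in FI, 3.18 in B, 3.18 in MS and -0.72 in SD, so harvest time is as open for B vs FI, SD vs MS and the comparisons with B, and an effect of stage or drying on the clock genes could give such values too.

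The dhurrin synthesis genes CYP79A1, CYP71E1 and UGT85B1 lay between 3.06 and 393 FPKM at booting in the soil bed and between 0.00736 and 4.17 FPKM in the drought columns, while the neighbouring genes GST1 and MATE2 were 4.64-fold and 2.81-fold lower in D1 than in B, although GST1 was 4.40-fold higher in D2 than in B. The values argue against separate normalization of the tables as the cause, since the median change of all genes from B to D1 was 0.0605 on the log2 scale. CYP79A1 and UGT85B1, 2 of the 3 genes, have the same start and end in both tables, so shifted gene ends are no cause for these. CYP71E1 starts at 1048570 in the development table and at 1048824 in the drought table. Equal ends do not show the exons or how reads were shared between rows, so different gene models stay open. The median change of the 3 genes was -7.98, but CYP71E1 and UGT85B1 were chosen for being among the largest decreases. CYP79A1, named beforehand, changed by -2.00, with 431 genes falling at least as far. At 3.06 FPKM in B and with a pseudocount of 1 FPKM, it could hardly fall further, so this rank says little. Its FPKM values differed 224-fold between B and D1, a ratio that rests on a value near 0. Growth in pots against a fertilised soil bed, the lack of watering and the time of day at harvest stay open, untested, and cannot be told apart in this design.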
